A study of Homo sapiens with 16 samples.

How the data were processed

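RNA of HCT116 cells was extracted with QIAzol and miRNeasy, labelled with Cy3 by the one-colour Quick Amp protocol and hybridised to Agilent arrays, per the labels. The P53 set used a 4x44K design and the FAO set an 8x60K design, so arrays of different sets were never put in 1 fit. The labels name the targets of the inhibitors and not the compounds. Acute treatments of the P53 set lasted 2 days and chronic ones 7 days. The spot values are an intensity per the file headers, written by Agilent Feature Extraction 10.5.1.1 (P53 set) and 10.7.3.1 (FAO set): background-subtracted, detrended and on a linear scale, with no normalization between arrays. The deposited series matrix holds the same intensity, rounded, spot for spot, so its scale, centring and direction are settled. Its column medians in the P53 set were 79.4, 70.4, 38.2, 40.7, 75.1, 77.4, 71.1 and 70.3, without and then with inhibitor in acute normoxia, acute hypoxia, chronic normoxia and chronic hypoxia. In the FAO set they were 26.1, 15.6, 24.8, 18.8, 54, 55.5, 56.5 and 59.7, without and then with inhibitor in acute hypoxia after chronic normoxia, acute hypoxia after chronic hypoxia, chronic normoxia and chronic hypoxia.

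Between 49.62 and 58.37 percent of spots per array were well above background in the P53 set and between 55.47 and 69.98 percent in the FAO set. The 75th percentile of the signal ranged from 476.7 to 971.4 and from 167.2 to 654.8, lowest under acute hypoxia in each set. No spot was saturated, and 87 to 119 (P53 set) and 269 to 398 (FAO set) spots per array carried outlier flags and were left out, as were control spots. The number of arrays limits the precision. Spots of 1 probe were averaged, which gave 41000 and 42405 probes. RefSeq accessions named 23434 and 24910 of them, current symbols 2317 and 1868 and synonyms 1043 and 587, and 14206 and 15040 had no match in the reference.

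Values were log2 of the processed signal minus the 75th percentile of the array. A probe was kept if well above background on at least 2 arrays of its set, and the probe with the highest mean stood for its gene symbol, which left 12299 and 15359 genes. The fit by limma 3.58.1 in R 4.3.3, with data.table in version 1.17.8, used 1 term per culture context and 1 for the inhibitor over the 8 arrays of a set, which leaves 3 residual degrees of freedom (2 in the tests of an inhibitor effect by oxygen). Variances were moderated, and a gene passed with a Benjamini-Hochberg adjusted p below 0.05. Matched pairs are arrays that share the context or the inhibitor state; they entered the fit through those terms. In the P53 set the acute cultures lay on 1 slide and the chronic ones on another, and the FAO set on 1 slide with the acute hypoxia arrays in their own row. The context terms hold the slide, so no slide block could be added, and fits within 1 slide were run in its place. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

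The 12 comparisons, the lists, the naming rule and the first alternatives were chosen before the data were examined. Named genes are, for each comparison, the 10 largest rises and 10 largest falls past the threshold (5 for differences of effects) that were well above background on every array of 1 arm and had the same sign in each matched pair, with clone, locus, open reading frame and LINC names left out. To these were added up to 4 members per list past the threshold, CDKN1A, MDM2 and GDF15 for P53 inhibition, CA9, VEGFA, NDRG1, SLC2A1 and PDK1 for hypoxia, and CPT1A, CPT2, PDK4, PLIN2 and ANGPTL4 for FAO inhibition. Where fewer than 5 of a direction passed, the 5 largest that were well above background on all 8 arrays with 1 sign in all pairs were named as not past the threshold. The 34 lists included HIF targets, glycolysis, p53 targets, fatty acid oxidation, PPAR targets, lipid droplet and storage, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, TCA cycle, mitosis and G2/M, DNA replication, ATF4 and amino acid response, unfolded protein response, AHR targets, NRF2 targets, heat shock, metallothioneins, autophagy and lysosome, epithelial and adhesion, mesenchymal transition, intestinal stem and WNT, interferon response, NF-kB and cytokines, immediate early genes, ribosome biogenesis, replication-dependent histones, histone demethylases, reference genes, the colon epithelial lineage of HCT116, and markers of endothelial cells, fibroblasts and leukocytes. Some genes that these rules select, and 1 list, are not reported here. The lists were tested by camera with its preset correlation of 0.01, adjusted over the 34 lists of a comparison. The overlap of the chronic hypoxia responses was set against that of independent lists.

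Alternatives set in advance were normexp (offset 50) with quantile normalization, quantile normalization alone, the values as deposited, no filter, a filter on all 8 arrays, the mean of probes, trend and robust moderation, each array left out, fits on only the 4 arrays compared or within 1 slide, fits without the inhibitor or the context term, the single pair without inhibitor, camera with an estimated correlation, and fry. Scaling to the spike-in probes detected on all arrays or to the percentile of detected probes, subsets of the FAO pairs and the overlap at unadjusted p were chosen after the data were seen. The fits were tested on simulated independent genes with the residual spread of each comparison, 100 each at a log2 change of 1 and 2. Of these 79 and 100 were recovered for acute hypoxia, 88 and 99 for P53 inhibition, 80 and 99 and 8 and 72 for chronic hypoxia in the P53 and the FAO set, 15 and 85 for acute against chronic hypoxia, 53 and 99 for FAO inhibition, 5 and 91 and 6 and 87 for acute hypoxia after chronic normoxia and after chronic hypoxia, 6 and 87 for earlier chronic hypoxia, 0 and 3 for the difference of acute responses, and 8 and 96 and 1 and 9 for the inhibitor effects by oxygen. Between 0 and 13 unchanged genes were called. The moved simulated list was called in all 12 comparisons (8 with an estimated correlation) and 0 unchanged ones were. This leaves the preset correlation untested.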

Results

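HCT116 cells, a human colorectal carcinoma line, were profiled on 16 one-colour arrays in 2 sets of 8, each condition on 1 array. The P53 set held acute normoxia, acute hypoxia (severe, 2 days), chronic normoxia and chronic hypoxia (mild, 7 days), each without and with an inhibitor of P53 signalling. The FAO set held chronic normoxia and chronic hypoxia, alone or followed by acute hypoxia, each without and with an inhibitor of fatty acid oxidation (FAO). Where acute hypoxia followed, the labels name the inhibitor with the chronic phase. They do not say whether it was present during acute hypoxia. Acute hypoxia in the P53 set raised VEGFA (4.74 ± 0.17) and HSPA5 (4.06 ± 0.20) and lowered ASPM (-5.20 ± 0.77) and IFIT1 (-5.64 ± 0.69) (log2 difference ± standard error, n = 2 arrays per arm, adjusted p from 0.000128 to 0.00239 by limma). After chronic hypoxia, CXCR4 (2.66 ± 0.36) and ANGPTL4 (2.51 ± 0.17) were among the largest values in the P53 set (adjusted p from 0.0729 to 0.0766) and ANKRD37 (3.18 ± 0.22) rose in the FAO set. Past an adjusted p of 0.05, acute hypoxia moved 7768 of 12299 genes in the P53 set, and 7382 and 6643 of 15359 in the FAO set after chronic normoxia and after chronic hypoxia. Chronic hypoxia moved 0 and 1, P53 inhibition 0 and FAO inhibition 0. No condition was replicated. The error of each test is the departure of the 8 arrays of a set from additive effects of culture and inhibitor, and the p-values measure the spread between these samples. Where a gene was not well above background on any array of 1 arm, its change is a bound, written as at least N-fold. It sets the mean of the brighter arm against the higher of the lowest signal well above background and the gene's own on each dimmer array. Signs of gene groups were compared under 5 other scalings (quantile, normexp with quantile, a percentile over detected probes, spike-in probes and the values as deposited), of which the detected-probe and spike-in ones were chosen after the data were seen.

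The acute hypoxia comparison asked which genes respond to 2 days of severe hypoxia. Among the largest rises that went the same way in both matched pairs were CREB3L2 (5.82 ± 0.12), H2AC18 (5.37 ± 0.13), H2AC7 (5.15 ± 0.14), RHOB (5.03 ± 0.41), SEMA7A (4.74 ± 0.29) and SEC24A (4.44 ± 0.25) (adjusted p from 0.000128 to 0.000426) besides VEGFA, which encodes a vascular growth factor. CREB3L2 encodes a membrane-bound transcription factor and RHOB a small GTPase. EID3 (at least 32.6-fold higher), RUBCN (at least 11.1-fold higher) and APOF (at least 6.08-fold higher) were not well above background in acute normoxia. PPP1R10 (-5.53 ± 0.15) and HASPIN (-5.08 ± 0.31) fell (adjusted p from 0.000128 to 0.000211), and after acute hypoxia BCDIN3D (at least 34-fold lower), TIGD5 (at least 30.4-fold lower), HYLS1 (at least 21-fold lower), PARS2 (at least 19.2-fold lower), ZNF786 (at least 13.7-fold lower) and CCDC71 (at least 6.6-fold lower) were not well above background. CA9, a carbonic anhydrase gene and HIF target, gave 0.51 ± 0.86 (adjusted p = 0.631). In limma 4048 genes rose and 3720 fell, of which 1702 and 2055 by at least 2-fold, and the pairs without and with inhibitor correlated at 0.9 across genes, which are not independent replicates. The split depended on the scaling. Rises and falls were 2913 and 4298 (quantile), 2937 and 4335 (normexp), 2956 and 4818 (detected-probe), 319 and 9943 (spike-in) and 770 and 7962 (deposited). Relative to the spike-in probes the median of all genes lay at -1.25, and in the values as deposited at -0.84, so the changes given are relative to the 75th percentile of each array.

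Hypoxia-inducible factor (HIF) and glycolysis genes rose. Of the HIF targets 32 of 34 rose, 1 fell and 1 did not pass. Their median was 1.66 (camera adjusted p = 7.58e-09, adjusted p = 0.7 with an estimated correlation). Examples were VEGFA (4.74 ± 0.17), HILPDA (3.70 ± 0.13), ERO1A (3.41 ± 0.15) and SLC2A3 (3.04 ± 0.37). Among glycolysis genes 23 of 24 rose, none fell and 1 did not pass. Their median was 1.20 and turned below 0 with spike-in scaling (camera adjusted p = 4.2e-07, adjusted p = 0.7 with an estimated correlation). Examples were ENO2 (2.53 ± 0.16), HK2 (2.29 ± 0.11) and ALDOC (2.17 ± 0.39). NDRG1, PDK1 and SLC2A1 rose by 1.66, 1.82 and 1.22, the last of these lying at -0.073 with spike-in scaling. In the unfolded protein response, 20 of 21 rose, none fell and 1 did not pass. Their median was 1.71 (camera adjusted p = 4.2e-07, adjusted p = 0.7 with an estimated correlation). Examples were DNAJB9 (3.48 ± 0.21), DNAJC3 (3.01 ± 0.13) and SEL1L (2.91 ± 0.29) next to the chaperone gene HSPA5. Of metallothionein genes, whose sequences are alike, 10 of 10 rose and none fell. Their median was 1.49 (camera adjusted p = 0.000181, adjusted p = 0.7 with an estimated correlation). Examples were MT1F (1.77 ± 0.19) and MT1X (1.68 ± 0.17). For replication-dependent histones, 10 of 13 rose, none fell and 3 did not pass. Their median was 1.41 (camera adjusted p = 0.0107, adjusted p = 0.7 with an estimated correlation). Examples were H2AC6 (2.69 ± 0.37), H1-2 (2.54 ± 0.26) and H2BC4 (1.92 ± 0.29), a family in which probes of 1 gene and its near-identical copies were not separated. The medians of the HIF, unfolded protein response, metallothionein and histone lists stayed above 0 with spike-in scaling, at 0.37, 0.41, 0.20 and 0.12, and that of glycolysis lay at -0.09. Adjusted over the list alone, the counts of these lists were the same.

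Stress and signalling genes went up and down. Of the immediate early genes 12 of 22 rose, 4 fell and 6 did not pass. Their median was 0.90 and turned below 0 with spike-in scaling (camera adjusted p = 0.0352, adjusted p = 0.7 with an estimated correlation). DUSP1 (4.29 ± 0.12) and JUN (3.18 ± 0.16) rose, while EGR1 (-2.46 ± 0.26) and EGR2 (at least 6.66-fold lower) fell. Among NF-kB and cytokine genes 8 of 15 rose, 1 fell and 6 did not pass. Their median was 0.91 and turned below 0 with spike-in scaling (camera adjusted p = 0.0246, adjusted p = 0.7 with an estimated correlation). Examples were CXCL8 (at least 5.63-fold higher), CCL20 (at least 4.43-fold higher), TNFAIP3 (2.06 ± 0.31) and NFKBIA (1.70 ± 0.15). For the ATF4 and amino acid response, 10 of 33 rose, 1 fell and 22 did not pass (8 higher and 1 lower adjusted over the list alone). Their median was 0.59 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.0369, adjusted p = 0.761 with an estimated correlation). Examples were STC2 (2.48 ± 0.38), ATF3 (2.46 ± 0.44) and GDF15 (1.46 ± 0.11). Of the NRF2 targets 13 of 19 rose, 2 fell and 4 did not pass. Their median was 0.69 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.0138, adjusted p = 0.7 with an estimated correlation). Examples were the ferritin genes FTL (2.10 ± 0.24) and FTH1 (1.74 ± 0.15). In the mesenchymal transition list 9 of 14 rose, 2 fell and 3 did not pass. Their median was 0.84 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.0523). Examples were CCN2 (4.09 ± 0.39), CCN1 (3.56 ± 0.22), LOXL2 (2.37 ± 0.36) and PLAUR (2.17 ± 0.25). Of autophagy and lysosome genes 13 of 25 rose, 4 fell and 8 did not pass. Their median was 0.35 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.0602). Examples were BNIP3L (2.02 ± 0.13), GABARAPL1 (1.76 ± 0.13) and MAP1LC3B (1.72 ± 0.18). Of the colon epithelial lineage 7 of 9 rose, 1 fell and 1 did not pass. Their median was 1.15 and turned below 0 with spike-in scaling (camera adjusted p = 0.0352, adjusted p = 0.7 with an estimated correlation). Of epithelial and adhesion genes 9 of 14 rose, 3 fell and 2 did not pass. Their median was 0.65 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.12). KRT8 (1.55 ± 0.19) and ELF3 (1.83 ± 0.19) rose, CLDN7 (1.19 ± 0.12) rose except with spike-in scaling, and CDX2 (-1.23 ± 0.14), an intestinal transcription factor gene, fell.

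Cell division, ribosome and interferon genes fell. For mitosis and G2/M, 27 of 41 fell, none rose and 14 did not pass (0 higher and 28 lower adjusted over the list alone). Their median was -1.99 (camera adjusted p = 1.93e-05, adjusted p = 0.7 with an estimated correlation). Examples were ASPM (-5.20 ± 0.77), KIF20A (-3.97 ± 0.88), AURKA (-3.96 ± 0.66) and MKI67 (at least 7.97-fold lower). For DNA replication, 2 of 40 rose, 19 fell and 19 did not pass (2 higher and 17 lower adjusted over the list alone). Their median was -0.54 (camera adjusted p = 0.00446, adjusted p = 0.7 with an estimated correlation). Examples were POLE2 (-2.52 ± 0.14), CHAF1A (-2.09 ± 0.20) and GINS3 (-1.87 ± 0.11). In ribosome biogenesis 2 of 26 rose, 17 fell and 7 did not pass. Their median was -0.79 (camera adjusted p = 0.000181, adjusted p = 0.7 with an estimated correlation). Examples were RRS1 (-2.75 ± 0.12), URB2 (-2.22 ± 0.14) and UTP15 (-1.82 ± 0.14). Of interferon response genes 2 of 24 rose, 14 fell and 8 did not pass. Their median was -1.52 (camera adjusted p = 0.0138, adjusted p = 0.7 with an estimated correlation). Examples were IFIT1 (-5.64 ± 0.69), OASL (-3.81 ± 0.47), IFIT2 (-3.14 ± 0.19) and OAS1 (at least 2.79-fold lower). These 4 medians were below 0 under every scaling. Of p53 targets 16 of 40 rose, 11 fell and 13 did not pass. Their median was 0.28 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.407). PLK2 (2.38 ± 0.12) and PLK3 (2.02 ± 0.12) rose and KITLG (-2.08 ± 0.25) and POLH (-2.11 ± 0.38) fell. Among AHR targets 2 of 7 rose, 2 fell and 3 did not pass. Their median was -0.04 (camera adjusted p = 0.896). CYP1B1 (at least 3.8-fold lower) fell. Of heat shock genes 4 of 12 rose, 4 fell and 4 did not pass. Their median was -0.01 (camera adjusted p = 0.816). Of intestinal stem and WNT genes 5 of 13 rose, 4 fell and 4 did not pass (6 higher and 4 lower adjusted over the list alone). Their median was 0.38 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.567). Of histone demethylases 5 of 13 rose, 3 fell and 5 did not pass. Their median was -0.06 (mean 0.06, camera adjusted p = 0.816). HSPH1 (-1.43 ± 0.12) and AXIN2 (-1.85 ± 0.38) fell and MYC (1.54 ± 0.14), KDM5C (1.40 ± 0.16) and KDM3A (1.32 ± 0.13) rose.

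Lipid and mitochondrial genes were examined in acute hypoxia as well. Of fatty acid oxidation genes 4 of 27 rose, 8 fell and 15 did not pass (4 higher and 7 lower adjusted over the list alone). Their median was 0.01 and turned below 0 under every other scaling (mean -0.10, camera adjusted p = 0.688). CPT2 (-2.60 ± 0.12) and SLC22A5 (-1.46 ± 0.14), which act in carnitine transfer and uptake, fell, and ACADVL (1.09 ± 0.17) and CPT1B (1.07 ± 0.26) rose. Of PPAR targets 5 of 10 rose, 1 fell and 4 did not pass. Their median was 0.41 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.407). ANGPTL4 (2.41 ± 0.17) and PLIN2 (1.05 ± 0.13) rose. In lipid droplet and storage 6 of 13 rose, 3 fell and 4 did not pass. Their median was 0.34 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.567). HILPDA rose and DGAT2 (at least 4.67-fold lower), LIPE (-1.92 ± 0.21) and GPAM (-1.54 ± 0.11) fell. Of cholesterol synthesis genes 2 of 26 rose, 8 fell and 16 did not pass. Their median was -0.37 (camera adjusted p = 0.15). MSMO1 (2.36 ± 0.16) and STARD4 (1.63 ± 0.29) rose. For fatty acid synthesis 3 of 13 rose, 2 fell and 8 did not pass. Their median was 0.03 and turned below 0 under every other scaling (camera adjusted p = 0.896). ME1 (1.0 ± 0.12) rose and FASN (-0.80 ± 0.21) fell. Among genes of oxidative phosphorylation 37 of 54 rose, none fell and 17 did not pass (38 higher and 0 lower adjusted over the list alone). Their median was 0.47 and turned below 0 with quantile, normexp, spike-in and deposited scaling (camera adjusted p = 3.01e-05, adjusted p = 0.7 with an estimated correlation). Examples were UQCRB (1.09 ± 0.17) and COX5B (0.98 ± 0.12). Of the TCA cycle 9 of 23 rose, 5 fell and 9 did not pass. Their median was 0.27 and turned below 0 with quantile, normexp, spike-in and deposited scaling (camera adjusted p = 0.407). IDH2 (1.35 ± 0.28) rose and DLAT (-1.09 ± 0.13) fell. Of reference genes 10 of 15 rose, 2 fell and 3 did not pass. Their median was 0.59 and turned below 0 with quantile, normexp, spike-in and deposited scaling (camera adjusted p = 0.0682). GAPDH (1.57 ± 0.12) rose and TBP (-1.47 ± 0.13) fell. With spike-in scaling ACADVL, CPT1B, PLIN2, ME1, UQCRB and COX5B lay below 0. Of markers of other cell types 1 of 3 fibroblast genes rose, 1 fell and 1 did not pass (1 higher and 2 lower adjusted over the list alone). Their median was -0.37 (mean 0.10, camera adjusted p = 0.816). For leukocytes 1 of 4 rose, none fell and 3 did not pass (0 higher and 0 lower adjusted over the list alone). Their median was 0.54 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.488). For endothelium 1 of 2 fell, none rose and 1 did not pass (0 higher and 0 lower adjusted over the list alone). Their median was -0.17 and turned above 0 with normexp scaling (camera adjusted p = 0.896).

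**Figure D1:**
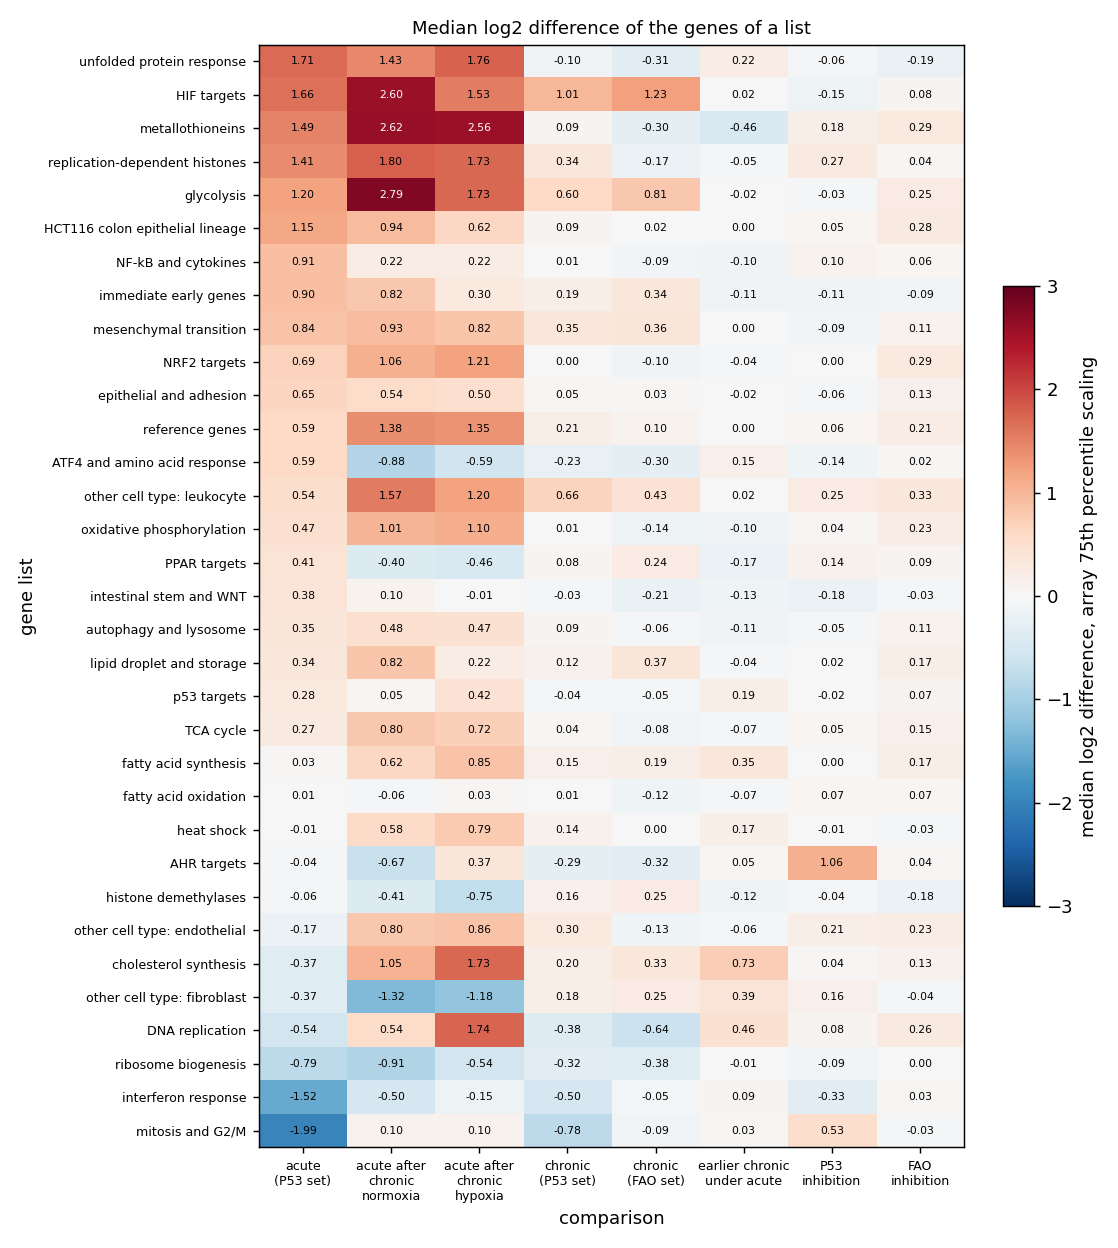
Median log2 difference of the members of gene lists (vertical axis) in 8 comparisons (horizontal axis), relative to the 75th percentile of each array. With spike-in scaling the medians shift with that of all genes, which lies at -1.25, -1.85 and -1.97 in the acute hypoxia columns, and most medians above 0 in those columns turn negative.

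Chronic hypoxia was compared with chronic normoxia in each set. In the P53 set, CA9 lay 2.91 ± 0.86 higher (n = 2 per arm), and CXCR4 (2.66 ± 0.36), ANGPTL4 (2.51 ± 0.17), SLC2A14 (2.43 ± 0.44), C2 (2.22 ± 0.49) and TNNT2 (2.16 ± 0.57) were among the largest values with the same sign in both pairs (adjusted p from 0.0729 to 0.127). DHRS2 (-3.28 ± 0.59), IFI6 (-2.53 ± 0.77), IFI27 (-2.24 ± 0.82), LONRF2 (-2.08 ± 0.25) and IFIT1 (-2.0 ± 0.69) lay lower (adjusted p from 0.0729 to 0.189), of which IFI6, IFI27 and IFIT1 are interferon-induced genes. NDRG1 gave 1.51, PDK1 1.14, SLC2A1 0.96 and VEGFA 0.52. Adjusted over the list alone, 30 of 34 HIF targets were higher and none lower, with 0 past over all genes (median 1.01, camera adjusted p = 1.31e-17, adjusted p = 0.552 with an estimated correlation, fry adjusted p = 0.0284). For glycolysis 19 of 24 were higher and 1 lower adjusted over the list alone, with 0 over all genes (median 0.60, camera adjusted p = 1.32e-09, adjusted p = 0.552 with an estimated correlation). Mitosis, DNA replication, ribosome biogenesis and interferon response had medians of -0.78, -0.38, -0.32 and -0.50 and no member past over all genes. Camera adjusted p was 2.18e-05, 1.13e-08, 3.46e-06 and 0.00223, and 0.869, 0.869, 0.552 and 0.869 with an estimated correlation. For DNA replication 0 were higher and 6 lower adjusted over the list alone. Inhibitor medians for mitosis and interferon were 2.06 and -1.14 in chronic normoxia, 0.75 and -0.33 in chronic hypoxia. So mitosis fell more in the pair with inhibitor and interferon genes in that without. The unfolded protein response gave median -0.10, camera adjusted p = 0.247. Of markers of other cell types, leukocyte genes gave median 0.66, camera adjusted p = 0.223, 1 higher and 0 lower adjusted over the list alone. Also called by camera was ATF4 and amino acid response (median -0.23, adjusted p = 0.00811, adjusted p = 0.869 with an estimated correlation). By limma 0 genes passed (smallest adjusted p 0.0729), with 2877 genes at an unadjusted p under 0.05 against 615 by chance and 0 to 3681 genes past the threshold under the other settings. Left out singly, 1 array changed the count, to 78 (chronic normoxia with inhibitor). With spike-in scaling the median of all genes was -0.38 and that of HIF targets 0.60.

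In the FAO set, ANKRD37 (3.18 ± 0.22, adjusted p = 0.0389), a HIF target, rose in both pairs with chronic hypoxia and was the 1 gene that passed. SLC2A3 (3.43 ± 0.37), SLC2A14 (3.32 ± 0.33), LOXL2 (3.0 ± 0.30), PPFIA4 (2.80 ± 0.88) and PAG1 (2.76 ± 0.39) were among the largest values without passing, and TAF9B (-2.53 ± 0.42), LONRF2 (-2.18 ± 1.1), NUPR1 (-2.09 ± 0.61), KISS1R (-1.87 ± 0.55) and KLK6 (-1.74 ± 0.26) were among the lowest (adjusted p from 0.069 to 0.888). CA9 gave 3.64 ± 0.42 (adjusted p = 0.0957), NDRG1 2.43, PDK1 1.55, SLC2A1 1.49 and VEGFA 0.43. Of 35 HIF targets 26 were higher and none lower adjusted over the list alone, and 1 over all genes (median 1.23, camera adjusted p = 6.77e-39, adjusted p = 0.0751 with an estimated correlation, fry adjusted p = 0.00942). Of 25 glycolysis genes 13 were higher adjusted over the list alone and 0 over all genes (median 0.81, camera adjusted p = 1.09e-19, adjusted p = 0.299 with an estimated correlation). DNA replication genes lay lower, 32 of 40 in both pairs (median -0.64, camera adjusted p = 1.46e-16, adjusted p = 0.731 with an estimated correlation), as did ribosome biogenesis (median -0.38, camera adjusted p = 2.86e-06, adjusted p = 0.485 with an estimated correlation). Mitosis (median -0.09, camera adjusted p = 0.557) and interferon response (median -0.05, camera adjusted p = 0.391, of the other sign with spike-in scaling) lay near 0. The cholesterol synthesis list gave median 0.33, camera adjusted p = 3.77e-05, adjusted p = 0.907 with an estimated correlation, 2 higher and 0 lower adjusted over the list alone, and markers of leukocytes median 0.43, camera adjusted p = 0.0316, adjusted p = 0.913 with an estimated correlation. Camera also called, by their medians, mesenchymal transition (0.36), immediate early genes (0.34), unfolded protein response (-0.31), ATF4 and amino acid response (-0.30), histone demethylases (0.25) and oxidative phosphorylation (-0.14) (adjusted p from 3.77e-05 to 0.0468, adjusted p from 0.321 to 0.932 with an estimated correlation). In limma 883 genes at an unadjusted p under 0.05 against 768 by chance were found, and 0 to 14 genes past the threshold under the other settings. Left out singly, 7 arrays changed the count, which fell to 0 without each acute hypoxia array.

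The response to chronic hypoxia was measured in both sets, which have no array in common. CA9 (2.91 and 3.64), SLC2A14 (2.43 and 3.32), SLC2A3 (2.27 and 3.43), PTPRR (2.74 and 2.94), CXCR4 (2.66 and 2.69), ANKRD37 (2.16 and 3.18), LOXL2 (2.15 and 3.0) and PAGE2 (2.36 and 2.99) were among the largest log2 differences in the P53 set and the FAO set, and PPFIA4 (1.87 and 2.80), ALDOC (1.81 and 2.72), ENO2 (2.01 and 2.30), EGLN3 (1.96 and 2.23), P4HA1 (1.80 and 2.22), NDRG1 (1.51 and 2.43) and ADM (1.36 and 2.55) followed. SLC2A3 and SLC2A14 encode close relatives of 1 glucose transporter and their probes were not tested for specificity. Lower in both were TMT1A (-2.30 and -1.98), CD22 (-1.48 and -1.51) and KLK6 (-1.16 and -1.74). These genes were ranked by their values in both sets, so those that the naming rule does not hold (PTPRR, PAGE2, TMT1A and CD22 among them) were chosen after their values were seen. The differences correlated at 0.676 (Spearman 0.69) across 11929 genes, which are not independent replicates. By limma no gene passed an adjusted p of 0.05 in both sets, by itself or with a fold of at least 2, and 2 passed with normexp, 13 among genes well above background on all arrays and 8 with trend and robust moderation. At an unadjusted p under 0.05, 303 genes were higher in both against 60.9 for independent lists, 137 lower in both against 21, and 6 opposite. With a fold of at least 2 as well, 84 were higher and 13 lower.

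**Figure D2:**
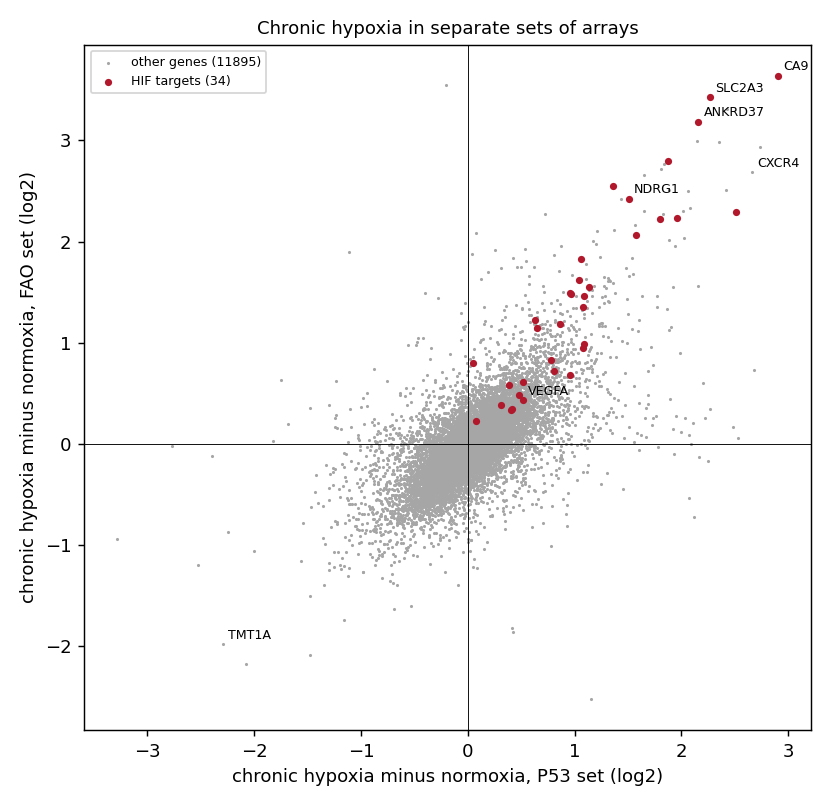
Log2 difference between chronic hypoxia and chronic normoxia in the P53 set (horizontal axis) and in the FAO set (vertical axis), 1 point per gene measured in both, with HIF targets in red. The 34 HIF targets lie above 0 in both sets, of which in the P53 set 4 turn below 0 with spike-in scaling and 2 each with quantile, normexp and deposited scaling, and in the FAO set 0 turn.

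Whether acute and chronic hypoxia differ was tested in the P53 set, each effect taken against its own normoxia on its own slide. CREB3L2 (5.65 ± 0.17), RHOB (5.30 ± 0.58), CCN2 (4.44 ± 0.55), H2AC18 (4.40 ± 0.19) and HSPA5 (4.40 ± 0.29) were among the largest differences toward acute hypoxia (adjusted p from 0.000932 to 0.0041, n = 2 arrays in each of 4 cultures), and PPP1R10 (-5.27 ± 0.22) and PARS2, which was not well above background after acute hypoxia, among the largest the other way. VEGFA differed by 4.23 ± 0.24 and HILPDA by 2.62 ± 0.19, while EGLN3, a HIF prolyl hydroxylase gene, differed by -2.45 ± 0.24. Of unfolded protein response genes 20 of 21 were higher, none lower and 1 did not pass. Their median was 1.65 (camera adjusted p = 4.66e-09, adjusted p = 0.661 with an estimated correlation). Examples were DNAJB9 (3.67 ± 0.30), SEL1L (3.02 ± 0.40) and DNAJC3 (2.95 ± 0.19). Of HIF targets 16 of 34 were higher, 1 lower and 17 did not pass. Their median was 0.67 and turned below 0 with spike-in scaling (camera adjusted p = 0.00144, adjusted p = 0.661 with an estimated correlation). Of metallothioneins 9 of 10 were higher, none lower and 1 did not pass. Their median was 1.41 (camera adjusted p = 0.000184, adjusted p = 0.661 with an estimated correlation). For mitosis and G2/M 5 of 41 were lower, none were higher and 36 did not pass (0 higher and 0 lower adjusted over the list alone). Their median was -1.24 (camera adjusted p = 0.0079, adjusted p = 0.84 with an estimated correlation). Examples were AURKA (-3.04 ± 0.94) and CKAP2 (-2.27 ± 0.65). For ribosome biogenesis 12 of 26 were lower, none were higher and 14 did not pass. Their median was -0.43 (camera adjusted p = 0.011, adjusted p = 0.661 with an estimated correlation). For the interferon response 1 of 24 was higher, 6 were lower and 17 did not pass (1 higher and 5 lower adjusted over the list alone). Their median was -0.98 (camera adjusted p = 0.231). By camera the other lists called, with their medians, were HCT116 colon epithelial lineage (1.07), NF-kB and cytokines (0.99), NRF2 targets (0.89), replication-dependent histones (0.89), ATF4 and amino acid response (0.82, other sign with spike-in), immediate early genes (0.55, other sign with spike-in and deposited), glycolysis (0.53, other sign with quantile, normexp, spike-in and deposited), oxidative phosphorylation (0.50, other sign with quantile, normexp, spike-in and deposited) and autophagy and lysosome (0.19, other sign with detected-probe, spike-in and deposited) (adjusted p from 8.48e-06 to 0.0483, adjusted p from 0.661 to 0.814 with an estimated correlation). By limma 2272 genes were higher and 2619 lower under acute hypoxia. Other scalings gave 1375 and 2652 (quantile), 1515 and 2656 (normexp), 1302 and 3433 (detected-probe), 273 and 7291 (spike-in) and 373 and 5429 (deposited). The median of all genes was -0.87 with spike-in scaling. With single arrays left out the count was 2521 (acute normoxia without inhibitor), 3041 (acute hypoxia without inhibitor), 3132 (acute hypoxia with inhibitor), 2179 (chronic hypoxia without inhibitor) and 1888 (chronic hypoxia with inhibitor).

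The FAO set asked how cells respond to acute hypoxia after a week of chronic normoxia or of chronic hypoxia. The acute hypoxia arrays had 2 more days of culture than the 7-day arrays they were compared with. They also lay in another row of the slide. Neither can be told apart from acute hypoxia in these comparisons. After chronic normoxia, ANKRD37 (6.51 ± 0.22), CXCR4 (5.64 ± 0.23), HILPDA (5.51 ± 0.28), ZNF584 (5.46 ± 0.24), MSMO1 (5.45 ± 0.29), WHRN (5.22 ± 0.37), CGAS (5.17 ± 0.29) and H2AC19 (5.17 ± 0.31) were among the largest rises of 1 direction in both pairs (adjusted p from 0.000353 to 0.000685, n = 2 per arm). The keratin genes KRT6A (6.79 ± 1.89) and KRT6C (at least 15.8-fold higher), close copies of each other, rose too. SNORA12 (-5.41 ± 0.40), DDX28 (-5.16 ± 0.25) and KLF3 (-5.07 ± 0.32) fell, and MBLAC2 (at least 19.6-fold lower), KRCC1 (at least 16-fold lower), LCMT2 (at least 15.9-fold lower), PRMT6 (at least 13-fold lower) and HYLS1 (at least 7.8-fold lower) were not well above background after acute hypoxia. NDRG1 rose by 3.70, CA9 by 3.69, PDK1 by 3.15, SLC2A1 by 2.74 and VEGFA by 2.58. Of HIF targets 32 of 35 rose, 1 fell and 2 did not pass. Their median was 2.60 (camera adjusted p = 4.42e-14, adjusted p = 0.327 with an estimated correlation). Of glycolysis genes 23 of 25 rose, none fell and 2 did not pass. Their median was 2.79 (camera adjusted p = 1.04e-11, adjusted p = 0.525 with an estimated correlation). Examples were ALDOC (5.09 ± 0.32), GPI (4.32 ± 0.28) and ENO2 (4.25 ± 0.28), and of metallothioneins 10 of 10 rose and none fell. Their median was 2.62 (camera adjusted p = 2.06e-06, adjusted p = 0.678 with an estimated correlation). These 3 medians stayed above 0 with spike-in scaling, at 0.70, 0.89 and 0.72. By limma 3856 genes rose and 3526 fell, and under other scalings 2362 and 4210 with quantile scaling, 2280 and 4294 with normexp and quantile scaling, 2879 and 4427 with detected-probe scaling, 12184 (12045 of them lower) with spike-in scaling and 230 and 10285 with the values as deposited. With single arrays left out 3562 (chronic normoxia then acute hypoxia with inhibitor), 2980 (chronic normoxia without inhibitor) and 2409 (chronic normoxia with inhibitor) passed.

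Stress, lipid and cell cycle genes also moved after chronic normoxia. Of ATF4 and amino acid response genes 6 of 35 rose, 18 fell and 11 did not pass (6 higher and 20 lower adjusted over the list alone). Their median was -0.88 (camera adjusted p = 0.00258, adjusted p = 0.678 with an estimated correlation). CHAC1 (-3.90 ± 0.34) and NUPR1 (-2.56 ± 0.61) fell. Of cholesterol synthesis genes 17 of 26 rose, none fell and 9 did not pass (19 higher and 0 lower adjusted over the list alone). Their median was 1.05 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 4.32e-05, adjusted p = 0.678 with an estimated correlation). Examples were INSIG1 (4.23 ± 0.37) and STARD4 (4.07 ± 0.37). Of mitosis and G2/M genes 8 of 41 rose, 9 fell and 24 did not pass. Their median was 0.10 and turned below 0 under every other scaling (camera adjusted p = 0.918). UBE2C (2.60 ± 0.35) and ANLN (2.28 ± 0.32) rose and ASPM (-2.31 ± 0.33) and CENPF (-2.30 ± 0.38) fell. CDKN1A (3.56 ± 0.58), which encodes the cell cycle inhibitor p21, rose, while of p53 targets 9 of 42 rose, 12 fell and 21 did not pass. Their median was 0.05 and turned below 0 under every other scaling (mean -0.11, camera adjusted p = 0.785). For fatty acid oxidation 3 of 28 rose, 7 fell and 18 did not pass (1 higher and 7 lower adjusted over the list alone). Their median was -0.06 (camera adjusted p = 0.526). SLC22A5 (-2.43 ± 0.32), CPT2 (-2.01 ± 0.24) and DGAT2 (at least 4.51-fold lower) fell. Of interferon response genes 2 of 27 rose, 8 fell and 17 did not pass. Their median was -0.50 (camera adjusted p = 0.154). An example was IFIT2 (at least 7.2-fold lower). Markers of leukocytes and blood moved with acute hypoxia: 7 of 10 rose, none fell and 3 did not pass (8 higher and 0 lower adjusted over the list alone). Their median was 1.57 and turned below 0 with spike-in scaling (camera adjusted p = 0.00507, adjusted p = 0.678 with an estimated correlation). Examples were CD68 (2.77 ± 0.77), HBA2 (2.66 ± 0.29) and PTPRC (1.94 ± 0.29). For fibroblasts 1 of 2 fell, none rose and 1 did not pass. Their median was -1.32 (camera adjusted p = 0.374). For endothelium 2 of 3 rose, none fell and 1 did not pass. Their median was 0.80 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.511). Other lists that camera called, with their medians, were ribosome biogenesis (-0.91) and, with the other sign under spike-in scaling, replication-dependent histones (1.80). Called with the other sign under spike-in and deposited scaling were unfolded protein response (1.43), reference genes (1.38) and NRF2 targets (1.06). So were oxidative phosphorylation (1.01), mesenchymal transition (0.93), immediate early genes (0.82), TCA cycle (0.80) and DNA replication (0.54). Camera adjusted p ran from 7.99e-08 to 0.0493, and from 0.525 to 0.796 with an estimated correlation. With quantile scaling these medians above 0 shrank, to 0.122 (oxidative phosphorylation), 0.191 (TCA cycle), 0.214 (reference genes) and up to 1.426 (histones).

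After chronic hypoxia, acute hypoxia raised MSMO1 (5.29 ± 0.29), WHRN (4.95 ± 0.37), ZNF584 (4.82 ± 0.24), CGAS (4.73 ± 0.29), FAM83A-AS1 (4.65 ± 0.79) and H2AC19 (4.61 ± 0.31) (adjusted p from 0.00122 to 0.00698) and BICC1 (at least 15.7-fold higher) and GDNF (at least 9.22-fold higher), which were not well above background before. SNORA12 (-5.79 ± 0.40) and HPS6 (-4.54 ± 0.24) fell, and MBLAC2 (at least 16.3-fold lower), HOMEZ (at least 13.5-fold lower), LCMT2 (at least 11.8-fold lower), CLDN23 (at least 10.4-fold lower) and PPARA (at least 8.63-fold lower) were not well above background afterwards, PPARA being a receptor gene of the fatty acid response. Of HIF targets 26 of 35 rose, 1 fell and 8 did not pass (27 higher and 1 lower adjusted over the list alone). Their median was 1.53 and turned below 0 with spike-in scaling (camera adjusted p = 7.06e-09, adjusted p = 0.65 with an estimated correlation). Examples were HILPDA (3.86 ± 0.28), ANKRD37 (3.34 ± 0.22) and ERO1A (3.06 ± 0.28). VEGFA rose by 2.21, CA9 by 1.74, PDK1 by 1.50, NDRG1 by 1.32 and SLC2A1 by 1.27, of which the last 4 lay below 0 with spike-in scaling, SLC2A1 also as deposited, and NDRG1 also as deposited and with quantile and normexp scaling. Of DNA replication genes 33 of 40 rose, none fell and 7 did not pass. Their median was 1.74 and turned below 0 with spike-in scaling (camera adjusted p = 2.26e-10, adjusted p = 0.65 with an estimated correlation). Examples were E2F1 (3.03 ± 0.26), TK1 (2.86 ± 0.37) and RRM2 (2.62 ± 0.43). Of cholesterol synthesis genes 19 of 26 rose, none fell and 7 did not pass. Their median was 1.73 and turned below 0 with spike-in scaling (camera adjusted p = 9.86e-08, adjusted p = 0.65 with an estimated correlation). Examples were STARD4 (3.48 ± 0.37) and INSIG1 (3.44 ± 0.37), and of the unfolded protein response 16 of 21 rose, none fell and 5 did not pass. Their median was 1.76 and turned below 0 with spike-in scaling (camera adjusted p = 3.31e-07, adjusted p = 0.65 with an estimated correlation). Examples were SDF2L1 (3.72 ± 0.22) and PDIA4 (3.06 ± 0.24). CDKN1A (3.68 ± 0.58) rose, and STC2 (-2.93 ± 0.35), CHAC1 (-2.55 ± 0.34) and SP5 (-2.36 ± 0.36) fell. Of markers of other cell types 5 of 10 leukocyte genes rose, none fell and 5 did not pass (6 higher and 0 lower adjusted over the list alone). Their median was 1.20 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.0161, adjusted p = 0.65 with an estimated correlation). For fibroblasts 1 of 2 fell, none rose and 1 did not pass. Their median was -1.18 (camera adjusted p = 0.454). For endothelium 2 of 3 rose, none fell and 1 did not pass. Their median was 0.86 and turned below 0 with spike-in and deposited scaling (camera adjusted p = 0.306). Camera also called, by their medians, metallothioneins (2.56) and, with the other sign under spike-in scaling, replication-dependent histones (1.73) and glycolysis (1.73). Called with the other sign under spike-in and deposited scaling were reference genes (1.35), NRF2 targets (1.21) and oxidative phosphorylation (1.1). So were fatty acid synthesis (0.85) and TCA cycle (0.72). Camera adjusted p ran from 2.99e-09 to 0.0345, and from 0.65 to 0.7 with an estimated correlation. With quantile scaling these medians shrank, to 0.079 (reference genes), 0.174 (TCA cycle), 0.178 (oxidative phosphorylation) and up to 1.463 (histones). By limma 3327 genes rose and 3316 fell. Other scalings gave 2121 and 3652 (quantile), 2156 and 3796 (normexp), 2456 and 4150 (detected-probe), 64 and 13044 (spike-in) and 189 and 9999 (deposited). The median of all genes lay at -1.97 with spike-in scaling, and at -1.85 in the comparison after chronic normoxia. With single arrays left out 1785 (chronic hypoxia then acute hypoxia without inhibitor), 903 (chronic hypoxia then acute hypoxia with inhibitor) and 2906 (chronic hypoxia with inhibitor) passed.

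**Figure D3:**
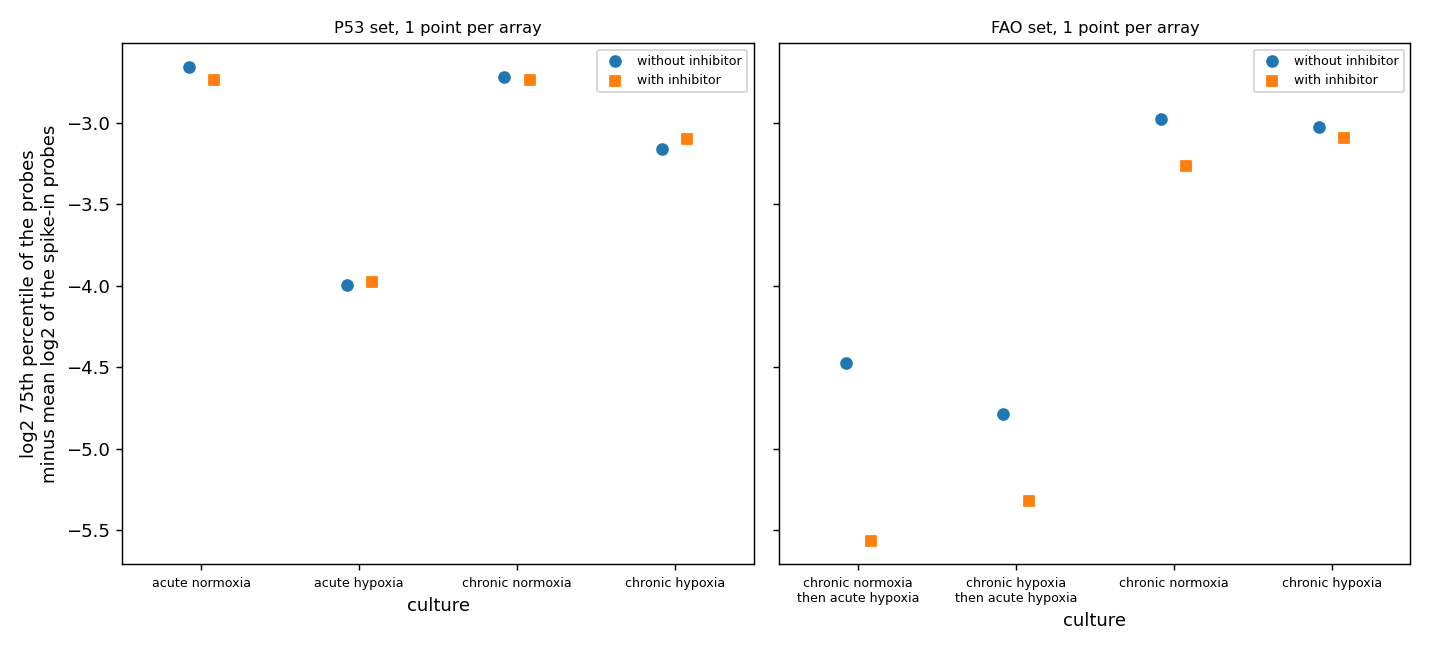
Log2 of the 75th percentile of all probes minus the mean log2 of the spike-in probes (vertical axis) by culture (horizontal axis), 1 point per array, for the P53 set (left) and the FAO set (right). Arrays of acute hypoxia lie lower in both sets, the difference that separates the 75th percentile and the spike-in scaling.

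Cells that met acute hypoxia after chronic hypoxia were compared with those that met it after chronic normoxia. Cholesterol synthesis genes lay higher after chronic hypoxia, 25 of 26 in both pairs (median 0.73, camera adjusted p = 1.26e-17, adjusted p = 0.986 with an estimated correlation), as did 35 of 40 DNA replication genes (median 0.46, camera adjusted p = 7.51e-12, adjusted p = 0.986 with an estimated correlation). HYAL1 (2.45 ± 0.79), H19 (1.97 ± 1.17), FGFBP1 (1.88 ± 0.42), PAG1 (1.85 ± 0.39) and CA9 (1.69 ± 0.42) and PRB1 (-1.98 ± 0.86), ZNF124 (-1.69 ± 0.71) and NMRK1 (-1.34 ± 0.33) were among the largest differences (adjusted p from 0.929 to 1, n = 2 per arm). NDRG1 (0.04), SLC2A1 (0.02), VEGFA (0.06) and PDK1 (-0.11) and the HIF targets as a list (median 0.02, camera adjusted p = 0.935) lay near 0. Besides these, camera called by their medians metallothioneins (-0.46), fatty acid synthesis (0.35), unfolded protein response (0.22) and p53 targets (0.19) (adjusted p from 0.000235 to 0.0127, adjusted p from 0.986 to 0.99 with an estimated correlation). Limma called 0 genes (smallest adjusted p 0.0927), with 662 genes at an unadjusted p under 0.05 against 768 by chance and 0 to 18 past the threshold under the other settings. The response to acute hypoxia itself was smaller after chronic hypoxia for ANKRD37 (by -3.17 ± 0.31), ADM (-2.80 ± 0.33) and ALDOC (-2.57 ± 0.45), and larger for TFRC (2.25 ± 0.88) and HRG (2.02 ± 0.41), all short of the threshold (adjusted p from 0.374 to 1). Adjusted over the list alone, 19 of 35 HIF targets responded less and none more, against 0 over all genes (median -1.06, camera adjusted p = 3.12e-29, adjusted p = 0.114 with an estimated correlation). For glycolysis the count was 11 adjusted over the list alone and 0 over all genes (median -0.94, camera adjusted p = 4.16e-16, adjusted p = 0.267 with an estimated correlation). DNA replication genes went the other way, 37 of 40 in both pairs (median 1.05, camera adjusted p = 2.16e-26, adjusted p = 0.585 with an estimated correlation). On the same arrays this contrast is the difference under acute hypoxia minus that between the chronic cultures. For HIF targets the former lay near 0 (median 0.02), so their smaller response mostly restates the higher start in chronic hypoxia. Between the chronic cultures ANKRD37 differed by 3.18, ALDOC by 2.72 and ADM by 2.55. Camera further called, by their medians, mesenchymal transition (-0.54), unfolded protein response (0.50), histone demethylases (-0.42), ATF4 and amino acid response (0.39), immediate early genes (-0.37), ribosome biogenesis (0.31), cholesterol synthesis (0.29) and p53 targets (0.25) (adjusted p from 1.78e-06 to 0.0101, adjusted p from 0.267 to 0.93 with an estimated correlation). In limma 0 genes passed this test of the difference (smallest adjusted p 0.374), with 665 genes at an unadjusted p under 0.05 against 768 by chance and 0 past the threshold under every other setting.

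P53 inhibition was compared over 4 matched pairs (n = 4 per arm). The p53 targets CDKN1A (0.17 ± 0.10), MDM2 (0.10 ± 0.09) and GDF15 (-0.12 ± 0.08) lay near 0 (adjusted p from 0.753 to 0.812). Of 40 p53 targets 7 were lower and 3 higher in all 4 pairs, and 0 passed over all genes or adjusted over the list alone (median -0.02, camera adjusted p = 0.661). CPA4 (1.62 ± 0.48), HAS3 (1.55 ± 0.30), ADGRF1 (1.40 ± 0.32), ALDH1A3 (1.37 ± 0.26) and GALNT5 (1.36 ± 0.46) and IGFBP3 (-1.99 ± 0.74), CCN2 (-1.45 ± 0.28), SLC1A3 (-1.21 ± 0.23), FGF18 (-1.18 ± 0.41) and IFIT1 (-1.08 ± 0.49) were among the largest values of 1 sign in all pairs (adjusted p from 0.539 to 0.698). AHR targets lay higher, 6 of 7 in all 4 pairs (CYP1A1 and CYP1B1 not well above background in acute hypoxia), with 0 past over all genes (median 1.06, camera adjusted p = 2.79e-06, adjusted p = 0.721 with an estimated correlation, 4 higher and 0 lower adjusted over the list alone). Lists of mitosis and G2/M (median 0.53, camera adjusted p = 6.36e-07, adjusted p = 0.727 with an estimated correlation) and histones (median 0.27, camera adjusted p = 0.000269, adjusted p = 0.727 with an estimated correlation, 1 higher and 0 lower adjusted over the list alone) lay above 0 and HIF targets below (median -0.15, camera adjusted p = 0.000392, adjusted p = 0.727 with an estimated correlation). Medians differed in sign by pair for mitosis (-0.37, -0.36, 2.06 and 0.75 in acute normoxia, acute hypoxia, chronic normoxia and chronic hypoxia) and HIF targets (-0.21, -0.22, 0.10 and -0.16). Other lists that camera called, with their medians, were interferon response (-0.33), intestinal stem and WNT (-0.18), metallothioneins (0.18), PPAR targets (0.14), ATF4 and amino acid response (-0.14), NF-kB and cytokines (0.10), ribosome biogenesis (-0.09), DNA replication (0.08), TCA cycle (0.05) and oxidative phosphorylation (0.04) (adjusted p from 0.00257 to 0.0389, adjusted p from 0.721 to 0.755 with an estimated correlation). Of these only intestinal stem and WNT and ribosome biogenesis kept 1 sign in all pairs. Limma called 0 genes (smallest adjusted p 0.371), with 896 at an unadjusted p under 0.05 against 615 by chance. The other settings gave 0 to 1 past the threshold.

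Whether the P53 inhibitor acts differently in hypoxic and in normoxic cultures was tested next. ATF4 and amino acid response genes gave larger values with inhibitor under hypoxia, 27 of 33 in both the acute and the chronic part (median 0.62, camera adjusted p = 1.82e-11, adjusted p = 0.759 with an estimated correlation). DDIT3 (2.28 ± 1.16), CHAC1 (2.26 ± 0.96) and SESN2 (1.80 ± 0.72) and DKK1 (-2.42 ± 0.93), PLCB4 (-1.79 ± 0.90) and PIP5K1C (-1.44 ± 0.17) were among the largest differences (adjusted p from 0.615 to 0.951), and DDIT3, a stress-induced transcription factor gene, differed by 4.29 in the acute and 0.27 in the chronic cultures. Mitosis and G2/M genes gave smaller values (median -0.57, camera adjusted p = 0.00466, adjusted p = 0.778 with an estimated correlation). Chronic cultures carried it: inhibitor medians were -0.37 and -0.36 in acute normoxia and hypoxia, 2.06 and 0.75 in chronic. Camera also called, by their medians, replication-dependent histones (-0.40), DNA replication (-0.31), metallothioneins (-0.28), unfolded protein response (0.27), reference genes (-0.15) and immediate early genes (0.15) (adjusted p from 7.41e-07 to 0.0361, adjusted p = 0.759 with an estimated correlation). In limma 0 genes passed (smallest adjusted p 0.0591), with 554 genes at an unadjusted p under 0.05 against 615 by chance and 0 past the threshold under every other setting.

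FAO inhibition gave changes of opposite sign in different pairs (n = 4 per arm). PDK4, which encodes a kinase that blocks pyruvate dehydrogenase, was 2.70 with the inhibitor in chronic normoxia, -3.52 in chronic hypoxia, and 0.67 and 0.24 in acute hypoxia after chronic normoxia and after chronic hypoxia. In the same order, the lipid droplet gene PLIN2 gave 2.77, -3.64, 0.46 and 0.98. ANGPTL4 gave 3.43, -1.53, 0.46 and 0.26, and CPT1A, for the entry step of fatty acid oxidation, 1.1, -1.71, 0.66 and 0.43. CPT2 gave 0.13 ± 0.17 over the 4 pairs. PRB1 (2.08 ± 0.61), FAM177B (0.98 ± 0.32) and FAM186B (0.96 ± 0.23) and KDM7A (-1.0 ± 0.40), KCNJ14 (-0.99 ± 0.39) and DICER1 (-0.95 ± 0.38) were among the largest values of 1 sign in all pairs (adjusted p = 0.719). In the chronic hypoxia pair, whose inhibitor labels are in doubt, PRB1 gave 2.71 and FAM186B 0.45, signs that would turn with the labels exchanged, and the other 4 lay between -0.079 and 0.018. Fatty acid oxidation genes (median 0.07, camera adjusted p = 0.899, of the other sign with quantile, normexp, spike-in and deposited scaling) and PPAR targets (median 0.09, camera adjusted p = 0.899, of the other sign with spike-in and deposited scaling) had 0 members past over all genes or adjusted over the list alone. DNA replication (median 0.26, camera adjusted p = 2.71e-05, adjusted p = 0.97 with an estimated correlation, of the other sign with spike-in and deposited scaling) and oxidative phosphorylation (median 0.23, camera adjusted p = 0.000286, adjusted p = 0.97 with an estimated correlation, of the other sign with spike-in and deposited scaling) lay above 0, at 0.18 and 0.032 with quantile and 0.14 and 0.034 with normexp scaling, with the median of all genes at -0.44 with spike-in scaling. By pair, in the order above, their medians were -0.20, 0.52, 0.44 and 0.23, and 0.06, -0.26, 0.74 and 0.38. Across genes the pairs correlated between -0.629 (chronic normoxia with chronic hypoxia) and 0.683 (both acute hypoxia pairs). Further lists called, with their medians, were leukocyte markers (0.33, other sign with spike-in), NRF2 targets (0.29, other sign with spike-in), metallothioneins (0.29, other sign with spike-in), glycolysis (0.25, other sign with spike-in and deposited), unfolded protein response (-0.19), histone demethylases (-0.18) and immediate early genes (-0.09) (adjusted p from 0.00398 to 0.0277, adjusted p = 0.97 with an estimated correlation). Of these further lists only histone demethylases kept 1 sign of the median in all pairs. In limma 0 genes passed (smallest adjusted p 0.719), with 357 genes at an unadjusted p under 0.05 against 768 by chance. Without the chronic hypoxia pair 0 passed, with 3137 at an unadjusted p under 0.05, and over the 2 acute hypoxia pairs alone 1745 passed, both chosen after the data were seen.

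Between cultures kept earlier in chronic hypoxia and in chronic normoxia, the values of ARRDC4 (3.46 ± 1.14), PRB1 (2.78 ± 0.62) and IGFBP3 (2.07 ± 0.67) and PDK4 (-3.33 ± 1.20), DAPP1 (-2.67 ± 1.04) and ANGPTL4 (-2.58 ± 1.0) were among the largest differences in the effect of FAO inhibition, all short of the threshold (adjusted p = 0.999). They rest in part on the chronic hypoxia pair, whose inhibitor labels are in doubt: between the chronic cultures and within acute hypoxia the differences were ARRDC4 6.33 and 0.59, PRB1 2.50 and 3.05, IGFBP3 3.51 and 0.64, PDK4 -6.22 and -0.43, DAPP1 -5.22 and -0.13, and ANGPTL4 -4.96 and -0.20. PPAR targets gave smaller values after chronic hypoxia (median -0.76, camera adjusted p = 1.21e-05, adjusted p = 0.89 with an estimated correlation). The part that uses the same pair carried most of it: the median was -1.63 between the chronic cultures and -0.18 within acute hypoxia. Besides these, camera called by their medians leukocyte markers (-0.67), NRF2 targets (-0.52), mitosis and G2/M (0.46), immediate early genes (0.42), lipid droplet and storage (-0.39), interferon response (0.36), oxidative phosphorylation (-0.32, other sign with spike-in), ATF4 and amino acid response (0.32), DNA replication (0.24) and unfolded protein response (0.22) (adjusted p from 1.37e-07 to 0.0467, adjusted p = 0.89 with an estimated correlation). Limma called 0 genes (smallest adjusted p 0.999), with 337 genes at an unadjusted p under 0.05 against 768 by chance and 0 past the threshold under every other setting on all arrays. With single arrays left out, which leaves 1 residual degree of freedom, 1 (chronic normoxia then acute hypoxia without inhibitor, chronic normoxia then acute hypoxia with inhibitor), 141 (chronic hypoxia then acute hypoxia without inhibitor, chronic hypoxia then acute hypoxia with inhibitor), 3 (chronic normoxia without inhibitor, chronic normoxia with inhibitor) and 10 (chronic hypoxia without inhibitor, chronic hypoxia with inhibitor) passed.

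**Figure D4:**
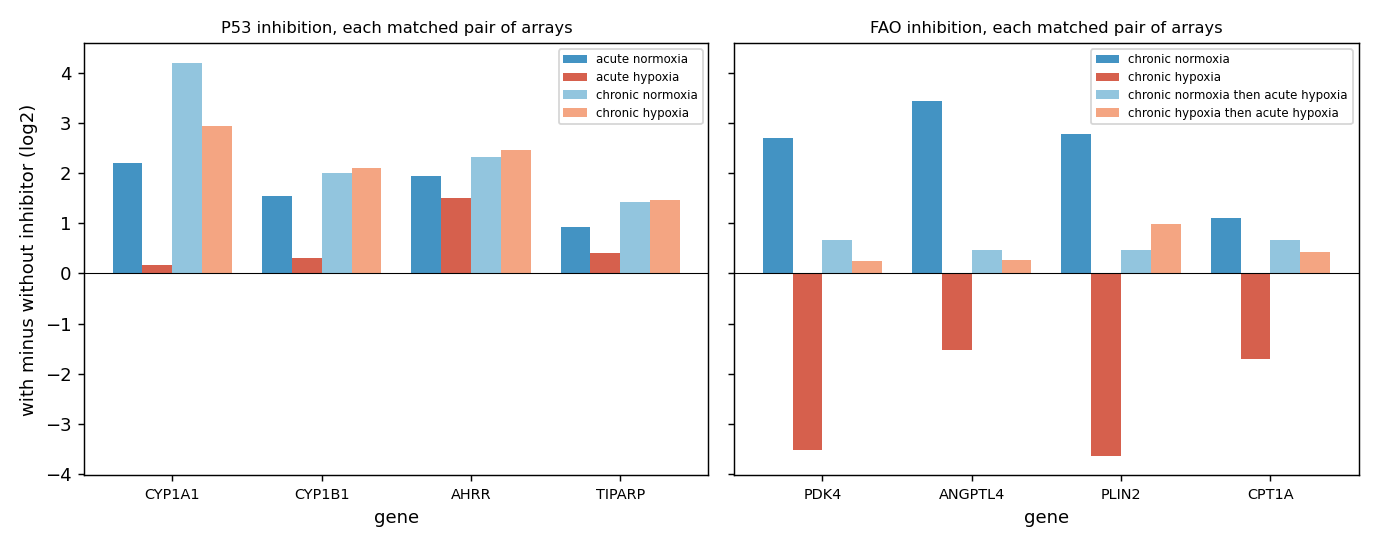
Log2 difference with minus without inhibitor (vertical axis) in each of the 4 matched pairs of a set, for 4 AHR target genes with P53 inhibition (left) and 4 PPAR target genes with FAO inhibition (right). Each bar is 1 pair of arrays, and the chronic hypoxia bars of the FAO set point down where those of chronic normoxia point up. The acute hypoxia bars of CYP1A1 and CYP1B1 come from signals not well above background, as does the AHRR signal without inhibitor.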

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

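The 3 tests on the spike-in probes were chosen after the result was seen, as were the spike-in scaling and the fits on subsets of the FAO pairs. Acute and chronic hypoxia differed in their effects, each against its own normoxia, in 4891 genes by the test of the difference. With FAO inhibition PDK4 gave 2.70 in chronic normoxia and -3.52 in chronic hypoxia, and PLIN2 2.77 and -3.64, opposite directions in cultures under the same contrast. The difference between these 2 cultures alone was not tested. The test of FAO inhibition by earlier oxygen, which averages it with that within acute hypoxia, gave PDK4 -3.33 ± 1.20 (adjusted p = 0.999). The spike-in probes, which enter the comparisons only through the spike-in scaling, were brighter on the acute hypoxia arrays than on their matched arrays, by 0.313 without and 0.505 with inhibitor in the P53 set, by 0.325 and 0.372 in the FAO set after chronic normoxia and by 0.582 and 0.555 after chronic hypoxia (log2).

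The response to FAO inhibition had opposite signs in chronic normoxia and chronic hypoxia over the whole set of genes. Dim probes do not account for it, since genes well above background on all 8 arrays correlated at -0.72 between these pairs. An exchange of the inhibitor labels of the 2 chronic hypoxia arrays may be 1 source: of the 8 assignments that part every pair, the 1 with only this pair exchanged gave 18 genes past the threshold, against 0 as labelled and 0 in the other 6. That count restates the pattern, since this pair correlated negatively with the other 3 (-0.629, -0.319 and -0.315). An exchange cannot be told apart from a response that reverses in chronic hypoxia, with each condition on 1 array, and the labels were used as deposited.

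Gene signal lay lower against the spike-in probes on every acute hypoxia array. The row of the slide is not the sole source: the smaller P53 set fall was -1.24 with both arms in 1 row of 1 slide. It may add to the larger FAO falls, where rows differed. Less labelled RNA put on the array is argued against by the spike-in probes themselves, which were brighter on each acute hypoxia array by at least 0.313. A lower share of polyadenylated RNA in the cells may be 1 source, with falls down to -2.30, but it cannot be told apart from RNA of lower quality or a smaller amount of RNA taken with the same spike-in, for which the files hold no values.

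Genes with ZNF names, most of which encode zinc finger proteins, fell with acute hypoxia as a group chosen after the values were seen: in the P53 set 178 of 314 fell and 42 rose (median -0.79), and in the FAO set 223 and 213 of 415 fell (medians -1.09 and -1.07). Dim probes do not account for the whole of it, since the median lay -0.716 from that of 10000 lists of other genes matched on level. Whether they add a share stays open. Among ZNF genes well above background on all 8 arrays the medians were -0.31, -0.58 and -0.60 (other such genes 0.12, 0.17 and 0.18). That filter drops genes that fell to background. The fall was not particular to the P53 set, the smaller FAO set median being -1.07. A response of these genes to acute hypoxia itself may remain as a hypothesis.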

How the results depend on the processing

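Spike-in and detected-probe scaling, subsets of the FAO pairs and the overlap at unadjusted p were tests chosen after the data were seen. The count for acute hypoxia stayed within 1.5 times of 7768 in every alternative, and P53 inhibition and the inhibitor effects by oxygen kept 0 genes except as given here. The cause of the changes below was not tested. Genes past the threshold for chronic hypoxia in the P53 set (0 in the fit as reported) were 32 with normexp and quantile, 3681 with spike-in scaling, 311 with the filter on all 8 arrays, 296 with trend and robust moderation and 35 with no inhibitor term. For chronic hypoxia in the FAO set (1) they were 3, 0, 14, 14 and 7 in the same order, and 0 with quantile, 0 as deposited, 0 with detected probes, 0 with no filter and 0 with only the 4 arrays compared. Both sets together (0) gave 2 with normexp and quantile, 13 with the filter on all 8 arrays, 8 with trend and robust moderation, 2 with no inhibitor term and 440 at unadjusted p. Acute against chronic hypoxia (4891) gave 7564 with spike-in scaling and 7523 with no filter. Acute hypoxia after chronic normoxia (7382) gave 12184 with spike-in scaling, and after chronic hypoxia (6643) 13108, and 10188 as deposited. Earlier chronic hypoxia (0) gave 2 with quantile, 2 with no inhibitor term and 18 with only the 4 arrays compared. P53 inhibition (0) gave 1 with trend and robust moderation and 0 within either slide, and FAO inhibition (0) gave 1745 with only the 2 contexts with acute hypoxia. Of 408 list tests 136 passed by camera, 0 with an estimated correlation and 71 with fry.

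With each array left out in turn, where a lone array is taken to vary like the others, the counts stayed 0 for P53 inhibition, its effect by oxygen, FAO inhibition, earlier chronic hypoxia and the difference of acute responses. They ranged over 5660 to 8285 for acute hypoxia, 0 to 78 and 0 to 14 for chronic hypoxia in the P53 and FAO sets, 1888 to 4735 for acute against chronic hypoxia, 2409 to 8269 and 903 to 7420 for acute hypoxia after chronic normoxia and after chronic hypoxia, and 1 to 141 for FAO inhibition by earlier oxygen. With spike-in scaling, signs turned in acute hypoxia for ACADVL (-0.21), CLDN7 (-0.10), COX5B (-0.31), CPT1B (-0.22), ME1 (-0.30), PLIN2 (-0.24), SLC2A1 (-0.073) and UQCRB (-0.20), and in acute hypoxia after chronic hypoxia for CA9 (-0.26), NDRG1 (-0.69), PDK1 (-0.50) and SLC2A1 (-0.73). There NDRG1 also turned with normexp and quantile (-0.01), with quantile (-0.02) and as deposited (-0.12), as did SLC2A1 as deposited (-0.16). Of 279 named values 225 kept direction and side of the threshold with spike-in scaling, 252 as deposited, 268 with quantile, 270 with normexp and quantile, 267 with trend and robust moderation and 277 with no filter. Slide as a block was not run, since each context lies on 1 slide. Signal over background limits the genes read in 1 arm only, which have bounds.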

Other observations

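The fit of the 2 acute hypoxia pairs alone was a test chosen after the result was seen. Within acute hypoxia, FAO inhibition raised CLIC3 (2.24 ± 0.25), FAM83A (2.0 ± 0.23), MYL2 (1.97 ± 0.22), LY6D (1.95 ± 0.27) and KRT16 (1.75 ± 0.23) and lowered SEC31B (-3.42 ± 0.30), GOLGA8A (-2.99 ± 0.23), MAT2A (-2.65 ± 0.31), LUC7L3 (-2.37 ± 0.25), NKTR (-2.32 ± 0.26) and DDX5 (-2.28 ± 0.26) (adjusted p from 0.00511 to 0.00982 by limma, n = 2 per arm), genes chosen after their values were seen among those well above background on all arrays. KRT16 encodes a keratin, MAT2A a methionine adenosyltransferase, and LUC7L3 and DDX5 RNA-processing proteins. In the chronic cultures without acute hypoxia CLIC3 gave 1.72 (normoxia) and -1.63 (hypoxia), FAM83A 2.18 and -1.76, and SEC31B 0.54 and -0.17. In that fit 1745 genes passed, 560 higher and 1185 lower, with 1 residual degree of freedom. Both arrays with inhibitor were dimmer than those without: the log2 of the 75th percentile against the spike-in probes was -5.56 against -4.48 after chronic normoxia and -5.32 against -4.79 after chronic hypoxia, and the spots well above background 55.47 against 61.95 and 57.57 against 60.95 percent.

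A hypothesis written in advance held that the P53 inhibitor also acts on AHR target genes. CYP1A1 gave 2.38 ± 0.62, CYP1B1 1.49 ± 0.31, AHRR 2.06 ± 0.17 and TIPARP 1.06 ± 0.20 over the 4 pairs (adjusted p from 0.371 to 0.584). Their median was 1.77, and by pair 1.75 in acute normoxia, 2.16 in chronic normoxia and 2.28 in chronic hypoxia, where each gene was higher. In acute hypoxia CYP1A1 and CYP1B1 were not well above background on either array and AHRR only with inhibitor, so that TIPARP alone (0.41) was read on both. The values of the other 3 cultures are in line with the hypothesis, which stays open for acute hypoxia, and the compound is not named. Other splits of the 8 arrays do not test chance for the count of genes past the threshold with P53 inhibition: the real count is 0, which all 32 fitted splits reach by construction. The highest other gave 7, by a split that parts only the 2 chronic pairs, as labelled.

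A second hypothesis written in advance held that the FAO inhibitor raises PPAR target genes. The median of PDK4, ANGPTL4, PLIN2 and CPT1A was 0.132, and by pair 2.74, -2.61, 0.56 and 0.35 in chronic normoxia, chronic hypoxia and acute hypoxia after each. Each of the 4 genes was higher in 3 of 4 pairs and lower in chronic hypoxia, where the hypothesis failed as labelled. It stays open only because that pair's labels are in doubt: exchanged, all 4 would lie above 0. For the count of genes past the threshold with FAO inhibition the splits do not test chance either, since all 32 fitted ones reach the real 0 by construction. The highest other gave 2187, by a split that parts only the 2 acute hypoxia pairs, as labelled, which is the contrast of the inhibitor within those pairs.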
